A study of Mus musculus with 10 samples.

How the data were processed

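Poly(A) RNA of 5 mouse trophoblast stem cell lines was sequenced in 10 libraries, 2 per line: lines 1 and 2 labelled Tet2+/-, lines 1 and 2 labelled Tet2-/-, and 1 wild type line. Per the labels, all lines were C57BL/6 and grew in 70% feeder-conditioned medium with 25 ng/ml FGF4 and 1 µg/ml heparin; RNA was selected with oligo(dT), and stranded libraries of about 300 bp were sequenced on an Illumina HiSeq. The read length is 100 in the sample labels and 125 in the series text. Per the submitters' processing notes, TopHat 1.3.3, Cufflinks 1.2.0, HTSeq 0.6.0, edgeR (no version) and genome build mm9 were used; their settings, and whether Cufflinks used the strand, are not given in the sources used here.

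The authors deposited, per library, raw read counts per RefSeq transcript in the format of HTSeq, with no normalization. The FPKM values that the authors deposited are in the format of a Cufflinks transcript table, per kilobase of transcript and scaled to the mapped fragments, with confidence bounds. The same deposited tables give the coverage, which is the mean depth of read bases per transcript base, and the transcript length in bases. They hold 28842 transcripts, of which 637 had no symbol and carried 0.574 to 0.684% of the FPKM; the FPKM of transcripts with 1 symbol were summed to 22517 genes, 10 of which had a failed status in a library and were kept. The count tables hold 29243 transcripts, 28160 of which matched a symbol, and the others held 0.216% of the counts.

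The deposited counts were checked against the FPKM. Counts on transcripts were 348686 to 684820 per library, or 2.86 to 3.29% of the 11219443 to 23947762 uniquely placed reads, while fragments estimated from the deposited coverage and length (at 200 bases each) came to 98.9 to 103% of them. Eomes had 0 counts in every library at 25.4 to 71.8 FPKM, Gapdh had 2 to 17 at 411 to 582 FPKM, and Xist had 45 to 173 at 52.5 to 124 FPKM. Tsix, which lies opposite Xist, had 834 to 3389 counts at 0.017 to 0.148 FPKM. Among 47 pairs of overlapping opposite-strand genes (at least 500 bp shared; 1 under 0.1 FPKM and the other over 10) the silent gene had over 100 counts in 27.7%, against 0.18% of 8312 silent genes with no such partner; it had the higher count in 19 pairs (40.4%), fewer than the share over 0.75 that was set as the mark of reversed counting, and the median count was 1.9 for the silent and 27.1 for the expressed gene. Only gene bodies, not exons, were known to overlap. Counting on the strand opposite to the transcripts would account for Tsix and Xist. The mark was not passed, but it could not decide, since the exons may not overlap. Counts were a median of 2.53% of the estimated fragments over genes with a mean of at least 1 FPKM. With 0 counts at Eomes, this argues against counting on the transcripts' own strand. Whether the opposite strand was counted at all genes stays open. FPKM replaced the counts as the main measure because the counts hold few of the reads and are near 0 at Eomes and Gapdh. For the same reason the tests on the counts, kept as alternatives, do not check the FPKM results gene by gene. Reads of overlapping genes on opposite strands may be shared in the FPKM.

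For genotypes, log2(FPKM + 1) was averaged per line and fitted with limma 3.58.1 in R 4.3.3 (1 mean per genotype, empirical Bayes with a trend, 2 residual degrees of freedom). For lines, the 10 libraries were fitted with 1 mean per line (5 residual degrees of freedom). The 10904 genes with a mean of at least 1 FPKM were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Genes were also counted that were called with 1 sign in every comparison of a line of a genotype with a line of the other. The replicate numbers were not used as pairs, since the labels give no shared batch and not every pair of lines passed the limit of 0.1 for the correlation of residuals of equal number: it was 0.0587 to 0.304 over 10 pairs, all positive, with 7 over 0.1. The positive correlations point to an effect shared by libraries of equal number, which the main tests on libraries did not model. The first library was the deeper in every line, and the cause of that effect was not tested. The 20 gene lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the 20 lists of a comparison.

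The comparisons, the gene lists, the alternatives and the rule for naming genes were set before the data were examined, with edgeR on counts as the test; limma on FPKM was an alternative there and became the main test. The rule names Tet2, Tet1, Tet3, Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l, then per genotype comparison up to 10 called genes in each direction, filled up with genes called with 1 sign in every line pair and ranked by their smallest change. For comparisons of lines within a genotype it names 5 genes in each direction by fold change, and for lists up to 4 called members or, with none called, 2 with the highest level; Rik, Gm, LOC and clone-like symbols are passed over. List members with no call between lines were instead chosen after their values were seen, from those called in every line pair.

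On simulated values with 67 genes changed 4-fold, limma between lines recovered 52.2% for Tet2-/- against Tet2+/-, 26.9% for Tet2-/- against wild type and 19.4% for Tet2+/- against wild type, with 0, 1 and 1 false calls over all sizes of change. Limma on libraries recovered 98.5% of 2-fold changes between Tet2-/- line 1 and the wild type line, with 6 false calls. Alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on the deposited counts (TMM, medians of ratios or upper quartiles, with and without a filter), limma-voom and limma on FPKM with the line as a random effect, libraries as replicates, a pseudocount of 0.1, no filter on FPKM, a filter met whichever line was left out (10698 genes), scaled FPKM, edgeR on the estimated fragments, chromosomes centred per library, and leaving out each line and each library. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are those of the deposited tables (mm9); strand and transcript GC content (99.8% of tested genes) came from an annotation of a later build, matched by name.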

Results

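Trophoblast stem cells are the self-renewing cells of the early placental lineage, and they are held undifferentiated in culture by FGF4, heparin and medium conditioned by feeder fibroblasts. Tet2 encodes an enzyme that oxidises 5-methylcytosine in DNA. RNA of mouse trophoblast stem cell lines of 3 Tet2 genotypes was sequenced after oligo(dT) selection: 2 Tet2+/- lines, 2 Tet2-/- lines and 1 wild type line, with 2 libraries per line and 10 libraries in all. Gene expression is given as the FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) that the authors deposited, and each line's mean ± SD is over its 2 libraries. The libraries held 11219443 to 23947762 uniquely placed reads, and 10525 to 10940 genes reached 1 FPKM in a library.

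The 2 libraries of a line differed less than libraries of different lines, with a root mean square log2 difference of 0.131 to 0.189 against 0.386 to 0.700 in the FPKM. In the deposited transcript counts, which hold few reads so that sampling weighs heavily, the variance within a line was 1.1 to 1.27 times that of sampling, an excess beyond chance in every line (chi-square p of at most 1.15e-08), and 2.51 to 8.98 times between lines. The line carries the genotype and was taken as its replicate, so each Tet2 mutant genotype had 2 replicates and the wild type had 1, which was assumed to vary like the others. Comparisons of single lines used the libraries as replicates; the labels do not say that these came from separate cultures, so their p-values measure only the spread between libraries, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes, and 10904 genes with a mean of at least 1 FPKM were tested.

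Tet2 (NM_001040400, mm9 chromosome 3, 133126641 to 133207354) was transcribed in every line, including those labelled Tet2-/-. Its level was 1.84 ± 0.13 FPKM in the wild type line, 1.48 ± 0.13 and 1.73 ± 0.039 in Tet2+/- lines 1 and 2, and 1.67 ± 0.085 and 1.13 ± 0.014 in Tet2-/- lines 1 and 2. The Tet2-/- lines differed from the Tet2+/- lines by a log2 fold change of -0.13 (SE 0.26; limma adjusted p = 0.989), which is within the spread between lines, and the sign turned to 0.035 without Tet2-/- line 2. The labels do not say which part of the gene was changed, and a gene-level FPKM does not show which exons were read, so the Tet2 level does not check the genotypes; lines are named by their labels throughout.

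Among the other enzymes of DNA methylation, Dnmt3a, a de novo methyltransferase, was lowest in the Tet2+/- lines. Dnmt3a stood at 1.65 ± 0.014 and 1.52 ± 0.18 FPKM in Tet2+/- lines 1 and 2, at 4.58 ± 0.36 and 2.57 ± 0.011 in Tet2-/- lines 1 and 2, and at 5.18 ± 0.0054 in the wild type line. Dnmt3b, the other de novo methyltransferase, was at 83.8 ± 0.73 FPKM in the wild type line and at 47.6 to 58.1 in the 4 mutant lines. Dnmt3l, their cofactor, was at 11.1 ± 0.81 FPKM in the wild type line and at 2.85 to 5.63 in the mutant lines. By limma on libraries, Dnmt3a was higher in every pair of a Tet2-/- with a Tet2+/- line and lower in both Tet2+/- lines than in the wild type, and Dnmt3b and Dnmt3l were lower in all 4 mutant lines than in the wild type. Limma between lines called none of the 3 (Dnmt3a, Tet2-/- over Tet2+/-, log2 fold change 0.79, SE 0.29, adjusted p = 0.989; Tet2+/- over wild type, -1.26, SE 0.35, adjusted p = 0.791). The maintenance methyltransferase Dnmt1 (54 to 66.8 FPKM in the line means) and the Tet2 paralogs Tet1 (1.75 to 3.19) and Tet3 (2.68 to 4.73) showed no difference between mutant genotypes beyond the spread between lines. Their Tet2-/- over Tet2+/- log2 fold changes were 0.16, -0.12 and -0.05; those of Tet1 and Tet3 changed sign without Tet2-/- line 2 or without Tet2+/- line 1. Of the 23 measured genes of the DNA methylation machinery list, 1 was higher and 2 were lower in every pair of a Tet2-/- with a Tet2+/- line.

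**Figure D1:**
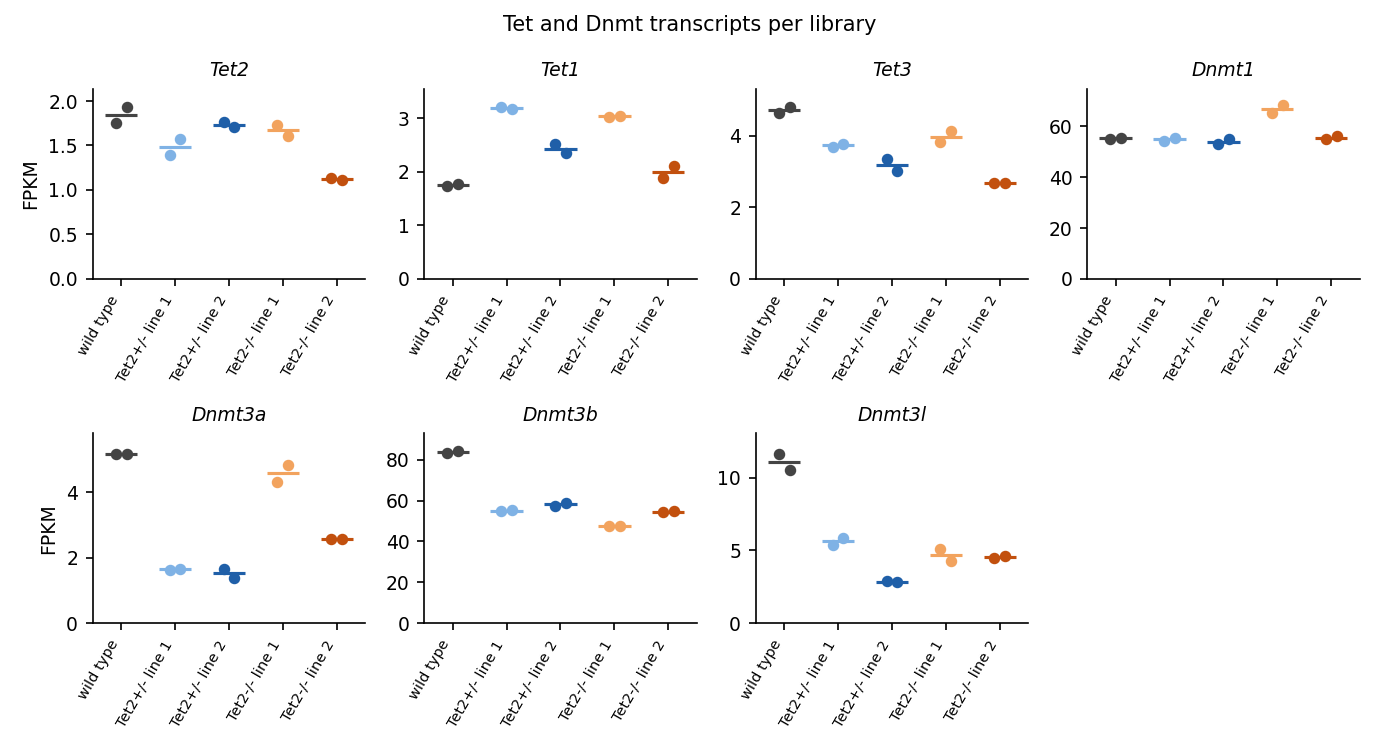
FPKM of Tet2, Tet1, Tet3, Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l in each library (points), with horizontal lines at the means of each line's 2 libraries. Tet2 lies between 1.13 and 1.84 FPKM in all line means, and Dnmt3b is at 83.8 in the wild type line against 47.6 to 58.1 in the mutant lines.

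The comparison of Tet2-/- with Tet2+/- lines asks which transcripts differ when both copies rather than 1 copy of Tet2 are changed. A single gene, AA465934, passed limma between lines; it falls outside the naming rule and was chosen after its values were seen. AA465934 is a non-coding transcript (NR_028363, chromosome 11, 83105201 to 83108139) and was at 31.4 ± 2.4 and 23.2 ± 4.3 FPKM in Tet2-/- lines 1 and 2 and at 17.4 ± 1.2 in the wild type line. It was at 0.12 ± 0.17 and 0.289 ± 0.41 in Tet2+/- lines 1 and 2, a log2 fold change of 4.56 (SE 0.23; limma adjusted p = 0.0323) between the mutant genotypes. The comparison had 0 calls without the filter on FPKM, on estimated fragments, and without either Tet2-/- line, Tet2+/- line 2, the first library of Tet2-/- line 2 or the second of Tet2+/- line 2. It had 18 without Tet2+/- line 1, 2 (with Gpr179) where the filter on FPKM had to be met whichever line was left out, and DESeq2 on the deposited counts called 4, edgeR 0, limma-voom 18, and limma on FPKM with the line as a random effect 6. At an unadjusted p under 0.05, where chance alone would name a share of 0.05 of the 10904 tested, limma named 305 genes. The 2 other pairings of the 4 mutant lines gave more, 645 and 447, so this number does not set the real grouping apart. On simulated values of the 10904 genes, limma recovered 4.48% of 2-fold, 52.2% of 4-fold and 75.8% of 8-fold changes between these groups, so most 2-fold changes were not detectable with 2 lines a genotype.

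Genes that separated all pairs of lines come next. In each of the 4 comparisons of a Tet2-/- with a Tet2+/- line, 553 genes were higher and 448 lower with 1 sign (limma on libraries); this is a count over these lines and not a test of genotype. The 2 other pairings of the 4 mutant lines gave more such genes, 1497 and 1053, against 1001 for the real grouping. Without Tet2+/- line 2 the count was 2988. Gpr179, an orphan receptor gene of the retina, was at 10.5 ± 0.63 and 9.03 ± 0.21 FPKM in Tet2-/- lines 1 and 2 and at 4.45 ± 0.29 in the wild type line. It was at 0.0214 in Tet2+/- line 1 and listed at 0 in both libraries of Tet2+/- line 2. Calca, which encodes calcitonin and its related peptide, was at 13.5 ± 0.12 and 23.8 ± 1 FPKM in the Tet2-/- lines and at 4.28 ± 0.8 and 0.643 ± 0.22 in the Tet2+/- lines. Mical2, an actin-oxidising enzyme, was at 6.18 and 6.41 FPKM in the Tet2-/- lines, at 1.91 and 1.97 in the Tet2+/- lines and at 1.76 in the wild type line. The lysosomal lipid hydrolase genes Lipa and Smpd1, the transcription factor Klf14 and the interferon-induced Oas1a were also higher in all 4 pairs, by log2 fold changes of 1.96, 1.87, 1.12 and 1.58. Slc35d2, Hist1h2bk and Fam57a completed the named set at 1.47, 1.14 and 1.42. All 10 had limma adjusted p between lines of 0.0625 (Gpr179) to 0.989.

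Genes lower in the Tet2-/- lines were led by Gsto1, a glutathione transferase gene. Gsto1 was at 563 ± 5.8 and 570 ± 11 FPKM in Tet2-/- lines 1 and 2, at 1495 ± 42 and 1336 ± 27 in Tet2+/- lines 1 and 2, and at 298 ± 4 in the wild type line (Tet2-/- over Tet2+/- log2 fold change -1.32, SE 0.15; limma adjusted p = 0.650). The lysosomal membrane gene Laptm5 was at 12.1 ± 0.1 and 19 ± 1.2 FPKM in the Tet2-/- lines against 42.3 and 56.5 in the Tet2+/- lines and 77 in the wild type line. The cysteine protease gene Ctsc was at 0.75 and 1.83 against 5.04 and 6.56, and the apolipoprotein gene Apoc1 at 78.1 and 82.9 against 174 and 149. Cxx1c, Pcx, Wbscr27, Slc22a17, Stag3 and B4galnt3 were lower in all 4 pairs too, with log2 fold changes of -1.5, -1.69, -0.89, -1.02, -1.29 and -1.26 and limma adjusted p of 0.989.

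**Figure D2:**
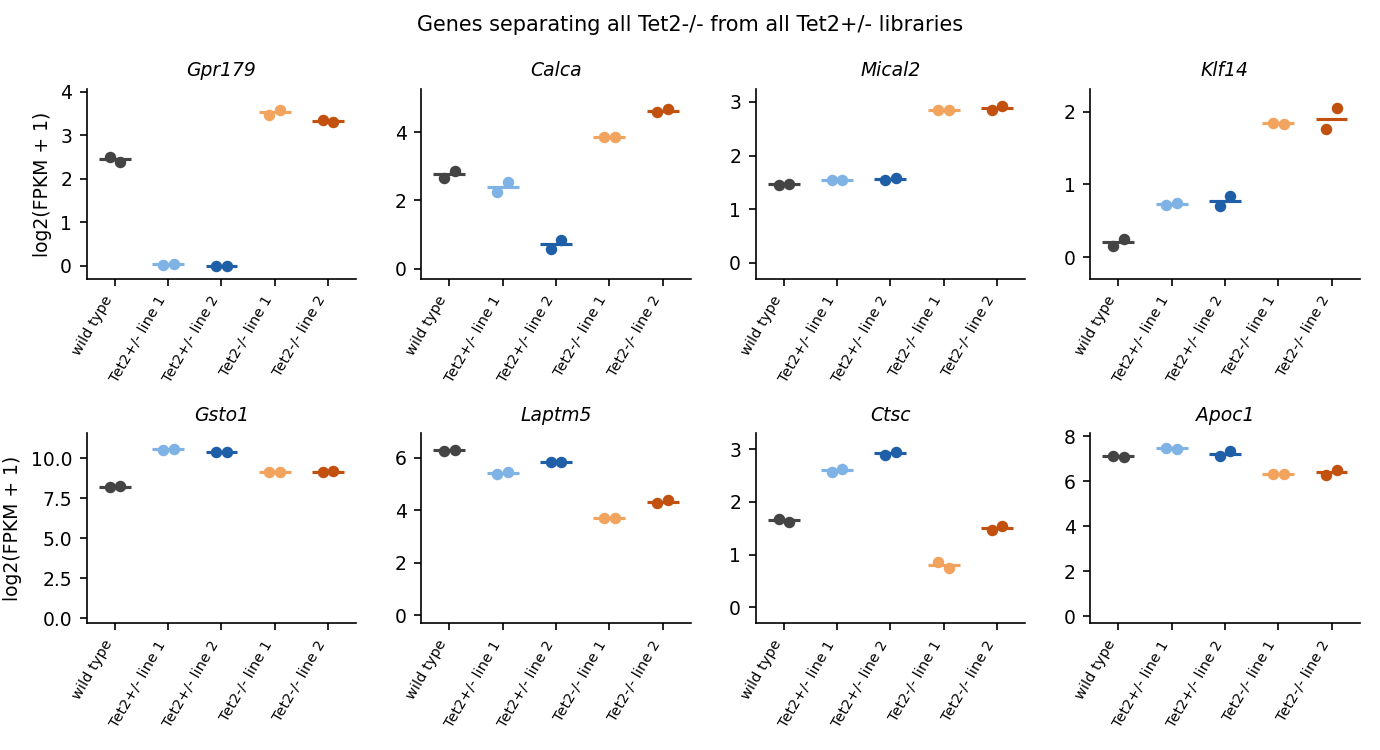
log2(FPKM + 1) of 4 genes higher (upper panels) and 4 genes lower (lower panels) in Tet2-/- than in Tet2+/- lines, per library (points), with horizontal lines at the line means. The wild type line lies between the mutant genotypes for Gpr179 and outside both for Klf14, Gsto1 and Laptm5.

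Cholesterol synthesis genes were lower in the mean of the Tet2-/- lines than in the Tet2+/- lines, mostly through Tet2-/- line 2. Of 23 measured members 6 were lower and 0 higher in every line pair (camera with a preset correlation, adjusted p = 2.10e-03; adjusted p = 0.689 with an estimated correlation). Higher and lower members of Tet2-/- line 2 numbered 0 and 20 against Tet2+/- line 1 and 1 and 18 against line 2, while those of Tet2-/- line 1 numbered 3 and 10, and 10 and 7 (median log2 fold change 0.02, camera adjusted p = 0.903). Sc4mol and Idi1, enzymes of the sterol and isoprenoid steps, had log2 fold changes of -0.54 (SE 0.16) and -0.54 (SE 0.19), and Hsd17b7 and Nsdhl of -0.40 and -0.32. Interferon response genes (camera adjusted p = 0.0170), mesenchymal genes (0.0213) and fibroblast markers (0.0213) were shifted up, all with adjusted p = 0.689 with an estimated correlation. In every line pair 2 of 24 interferon response genes were higher (Oas1a and Ifi35), 3 of 19 mesenchymal genes (Serpine1, Itga5 and Lgals1) and 1 of 7 fibroblast markers (Tagln), and none was lower. The interferon and fibroblast shifts rested on Tet2+/- line 2: without it they changed sign, with camera adjusted p of 0.602 and 0.997. Of the 8 RNA quality genes, Hist1h1c was higher in every line pair (log2 fold change 1.00). None of the members of any list was called by limma between lines, over all genes or adjusted over the list alone.

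The placental lists held no call between the mutant genotypes. In every pair of a Tet2-/- with a Tet2+/- line 1 of 27 trophoblast stem cell factors was higher (Smarca4) and 2 were lower (Duox2 and Tfap2c), with a camera adjusted p of 0.0696. Higher and lower members numbered 1 and 0 of 21 FGF-ERK response genes (adjusted p = 0.718), 1 and 1 of 14 trophoblast giant cell genes (0.236), 2 and 0 of 10 spongiotrophoblast and glycogen cell genes (0.236) and 2 and 0 of 15 syncytiotrophoblast genes (0.149). They numbered 2 and 3 of 45 imprinted genes (0.149), where Ndn had a log2 fold change of 1.98 (SE 0.80) and Peg3 of -0.48 (SE 0.22), and 2 and 1 of 11 germline genes silenced by DNA methylation (0.508). Among markers of other cells and states, 3 and 0 of 11 pluripotent stem cell markers (0.209), 1 and 0 of 12 endoderm markers (0.209), 2 and 0 of 29 epithelial genes (0.209), 1 and 3 of 32 cell cycle genes (0.237) and 1 and 1 of 26 p53 target genes (0.302) moved in every pair. Of 27 hypoxia and glycolysis genes 6 were higher and 0 lower, among them Ldha and Pfkl at log2 fold changes of 0.37 and 0.34 (camera adjusted p = 0.0795). The DNA methylation machinery (0.355), the 6 measured X inactivation and Y-linked genes (0.737) and the 8 RNA quality genes (0.894) were not called. The median (0.02) and the mean (-0.14) of the germline genes differed in sign, and the RNA quality genes had a negative median (-0.14) and mean (-0.02) with the test pointing up.

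Against the wild type line, genes of the FGF-ERK response were higher in both Tet2-/- lines. This comparison asks what sets the lines with both copies of Tet2 changed apart from cells with neither changed. Of 21 measured members 16 were higher and 2 (Fos and Spry1) lower in both lines (camera adjusted p = 2.97e-07 with a preset correlation; adjusted p = 0.628 with an estimated correlation; 1 member called when adjusted over the list alone). Fosl1, an AP-1 factor, was at 8.86 and 18.4 FPKM in Tet2-/- lines 1 and 2 and at 1.09 in the wild type line. The ETS factor gene Etv4 was at 25.2 and 26.7 against 5, the phosphatase gene Dusp6 at 21.4 and 31.3 against 9.06, the feedback inhibitor gene Spry4 at 5.5 and 8.77 against 1.07, and Ccnd1 at 16.4 and 24 against 4.51. Fos stood at 43.8 and 41.5 FPKM against 172 in the wild type line. In the same comparison 4 of 8 RNA quality genes were lower in both lines and 0 higher: Malat1, Neat1 and the histone genes Hist1h1c and Hist1h2bc, by log2 fold changes of -0.79, -0.64, -0.82 and -0.71. Mesenchymal genes were shifted up too (11 higher and 1 lower of 19; camera adjusted p = 4.31e-05), with Serpine1 at 447 and 562 FPKM against 115 and Sparc at 678 and 514 against 177. So were trophoblast giant cell genes (6 and 1 of 14; 7.51e-03, and 5.56e-03 with the 9 members that met the filter on FPKM whichever line was left out), with Mmp9 at 28.8 and 31.2 against 4.69 and the transcription factor Hand1 at 785 and 553 against 224, and germline genes silenced by DNA methylation (5 and 2 of 11; 0.0197), led by Rhox9 at 146 and 216 against 31.1. With an estimated correlation their adjusted p were 0.628, 0.789 and 0.628, and adjusted over the list alone 2 members of each were higher and 0 lower. The 11 germline genes are those of 61 with FPKM values that met the filter. Members under a mean of 1 FPKM were not tested, so the germline shift covers only members expressed in these lines.

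**Figure D3:**
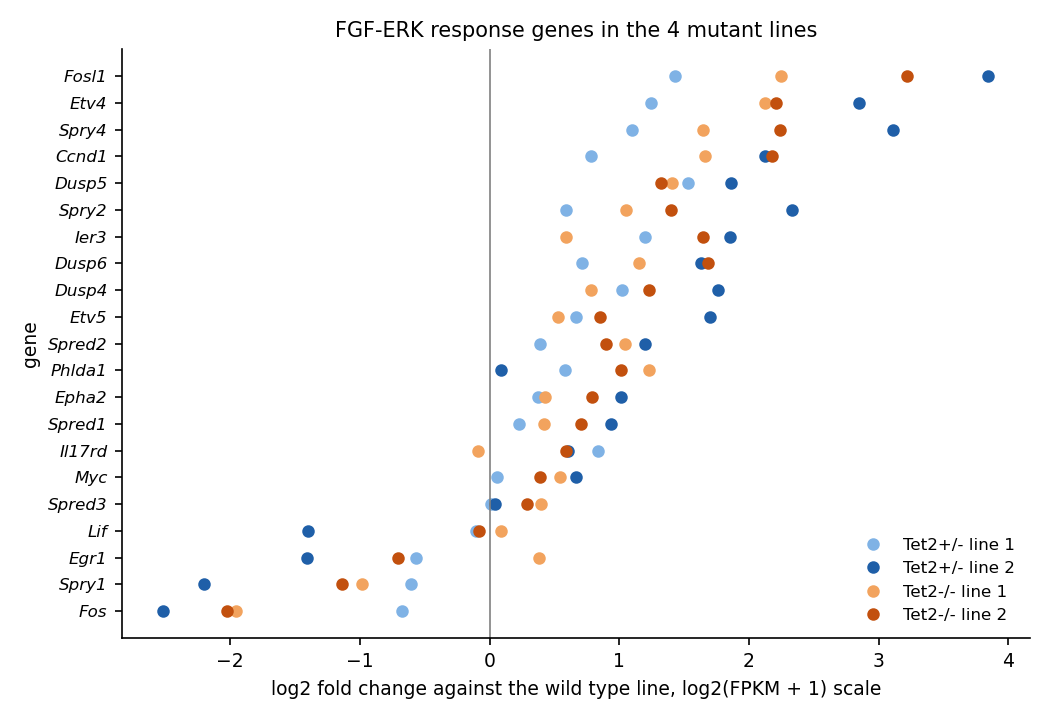
log2 fold change of the 21 measured FGF-ERK response genes in each mutant line against the wild type line (points). Most members lie above 0 in all 4 lines, and Fos and Spry1 lie below 0 in all 4.

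The wild type line lacked several transcripts that the Tet2-/- lines had. H19, an imprinted non-coding RNA (NR_001592, chromosome 7, 149761437 to 149764051), was at 137 ± 1.8 and 621 ± 13 FPKM in Tet2-/- lines 1 and 2 and at 0.841 ± 0.64 in the wild type line (log2 fold change 7.36, SE 0.91; limma adjusted p = 0.616). The imprinted Meg3, Rian, Mirg and Ndn were likewise higher in both Tet2-/- lines, with log2 fold changes of 5.10, 4.74, 3.71 and 3.21. Car4, a carbonic anhydrase, was at 55.2 and 42.2 FPKM against 3.58 (log2 fold change 3.43, SE 0.27; adjusted p = 0.163), and Ube2l6, the conjugating enzyme of the ubiquitin-like ISG15, at 14.3 and 12.1 against 0.485. Zfp512, Hn1 and the natriuretic peptide gene Nppb also exceeded the wild type line, by 3.13, 4.67 and 2.74 on the log2 scale. In the other direction the neighbouring Wnt6 and Wnt10a (chromosome 1) were lower: Wnt6 was at 23.9 and 28.6 FPKM against 146 ± 9.1, and Wnt10a at 0.174 and 0.305 against 4.79. Xlr5c, the adhesion receptor gene Icam1, Ifitm1, Ildr1, Laptm5, Fos, As3mt and Hsd17b14 were lower as well, with log2 fold changes from -1.99 (Fos) to -2.55 (Xlr5c).

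In all, 1890 genes were higher and 2285 lower in both Tet2-/- lines than in the wild type line by limma on libraries (2994 and 3141 for line 1, 2958 and 4154 for line 2). Scaling changed this split: with medians of ratios it was 2166 and 2009 (3107 and 3009 for line 1, 3559 and 3517 for line 2), and with upper quartiles 1914 and 2279 (2753 and 3467, 3349 and 3700). Limma between lines called 0 genes, with 652 at an unadjusted p under 0.05. Chance alone would put a share of 0.05 of the 10904 tested genes under that limit. DESeq2 on the deposited counts called 14, edgeR 0 and limma-voom 52, and limma on FPKM with the line as a random effect called 72. Unchanged genotypes simulated with 1 shared wild type line, as described below, gave 3146 genes of 1 sign in both Tet2-/- lines, against 4175 here. With a single wild type line, a difference of the genotype and a difference of that line are confounded in this and the next comparison.

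The remaining lists were not called in Tet2-/- lines against the wild type. Higher and lower members in both lines were 13 and 6 of 27 trophoblast stem cell factors (camera adjusted p = 0.116), with Esrrb at 60.3 and 84.1 FPKM against 25.6 and Id2 lower by a log2 fold change of -1.05. They were 11 and 13 of 45 imprinted genes (0.784; median log2 fold change -0.05, mean 0.45), 1 and 6 of 23 DNA methylation machinery genes (0.116), 3 and 5 of 10 spongiotrophoblast and glycogen cell genes (0.857) and 3 and 6 of 15 syncytiotrophoblast genes (0.864; median -0.08, mean -0.12, test up). They were 4 and 6 of 11 pluripotent stem cell markers (0.648), 6 and 3 of 12 endoderm markers (0.113), 4 and 1 of 7 fibroblast markers (0.201), 7 and 6 of 29 epithelial genes (0.566; median -0.07, mean 0.04), 3 and 10 of 32 cell cycle genes (0.566) and 8 and 6 of 26 p53 target genes (0.760; median 0.02, mean -0.01). They were 5 and 0 of 24 interferon response genes (0.0667), 7 and 3 of 27 hypoxia and glycolysis genes (0.464), 3 and 3 of 23 cholesterol synthesis genes (0.784; median 0.04, mean -0.02) and 0 and 3 of 6 X inactivation and Y-linked genes (0.566). RNA quality genes, described above, numbered 0 and 4 of 8 (0.487). Adjusted over the list alone, 1 member each of the spongiotrophoblast, syncytiotrophoblast, imprinted and epithelial lists was higher, and 0 members of the others.

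Tet2+/- lines also differed from the wild type line in FGF-ERK response genes and, more so in line 2, in trophoblast stem cell factors. This comparison asks what accompanies a change of 1 copy of Tet2. Of 21 FGF-ERK response genes 14 were higher and 3 lower in both lines (camera adjusted p = 8.28e-06; adjusted p = 0.653 with an estimated correlation; 1 called when adjusted over the list alone). Fosl1 was at 4.58 and 28.9 FPKM in Tet2+/- lines 1 and 2, Etv4 at 13.3 and 42.3 and Spry4 at 3.45 and 16.9. Of the RNA quality genes, Hist1h1c and Hist1h2bc were lower in both lines (log2 fold changes -1.81 and -1.26) and Rpph1 higher (1.34). Trophoblast giant cell genes were shifted up (6 higher and 2 lower of 14; adjusted p = 2.03e-04; 2 adjusted over the list alone), with Hand1 at 548 and 612 FPKM. Of these 14, 5 met the filter on FPKM only through Tet2+/- line 2 (Prl3d1, Prl3d3, Prl2c2, Prl2c3 and Prl7a1); with the other 9 the adjusted p was 8.90e-03. The median log2 fold change of the 14 was 0.54 in line 1 and 2.60 in line 2. For the other 9 it was 1.125 and 1.447, with camera adjusted p of 3.05e-03 in line 1 and 0.0814 in line 2. Of 27 trophoblast stem cell factors 14 were higher and 6 lower (adjusted p = 5.67e-03, with 0 called when adjusted over the list alone). Esrrb was at 54.5 and 106 FPKM, Eomes at 37.8 and 70.2 against 25.5 in the wild type line, and Duox2 at 31.3 and 62.3 against 6.02. Line 1 had 15 higher and 10 lower members (camera adjusted p = 0.0465, and 0.0682 with the filter met whichever line was left out). Line 2 had 18 and 7 (1.97e-03, and 6.7e-03 with that filter). Cdx2 was lower than in the wild type in line 1 and higher in line 2 (log2 fold changes -0.48 and 0.85). Germline genes were called as well (5 and 1 of 11, adjusted p = 0.0143, with 2 called when adjusted over the list alone). So were cholesterol synthesis genes (10 and 2 of 23, 0.0198) and mesenchymal genes (6 and 1 of 19, 0.0218). The 11 germline genes were again those of 61 that met the FPKM filter. Single lines were tested with the filter met whichever line was left out. Line 1 kept all these calls (camera adjusted p = 0.0476, 3.90e-04 and 6.79e-04). Line 2 kept none (0.183, 0.287 and 0.287), with 6 and 3, 11 and 7, and 9 and 7 members higher and lower. Sc4mol was at 89.5 and 85.8 FPKM against 45.9, and Idi1 at 34.5 and 42.4 against 21.2. With an estimated correlation the adjusted p of the last 5 lists were 0.749, 0.781, 0.653, 0.781 and 0.653.

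H19 was at 247 ± 4 and 507 ± 9.4 FPKM in Tet2+/- lines 1 and 2 (log2 fold change over the wild type 7.64, SE 0.91; limma adjusted p = 0.368). Car4 was at 64.1 and 50.5 FPKM (3.66, SE 0.27; adjusted p = 0.114), the homeobox gene Rhox9 at 206 and 363, and Ube2l6 at 8.87 and 8.33. The protease inhibitor gene Serpinb9b, Zfp512, the oxidase gene Duox2, Gsto1, the transglutaminase gene Tgm2 and Mid1 were higher too, by log2 fold changes of 2.82, 2.53, 2.69, 2.24, 2.62 and 2.22. Genes lower in both Tet2+/- lines included Gpr179 (-2.43, SE 0.27), Adck5 at 6.29 and 5.91 FPKM against 31.9, and Crip1 at 59 and 6.39 against 284. Slc35d2, Sorbs3, Stx1b, Wnt10a, the imprinted Zdbf2, Ifitm1 and Clip3 were lower by log2 fold changes between -1.96 (Zdbf2) and -2.39 (Ifitm1). Over all genes 1531 were higher and 2100 lower in both lines (2578 and 3359 for line 1, 3549 and 4192 for line 2), and 5937 genes when line 1 stood alone. With medians of ratios the split was 1818 and 1741 (2988 and 2827, 3888 and 3875), and with upper quartiles 1654 and 1895 (2980 and 2833, 3340 and 4367). Limma between lines called 0, with 655 at an unadjusted p under 0.05; without Tet2+/- line 1 it called 55. DESeq2 on the deposited counts called 18, edgeR 0 and limma-voom 99, and limma on FPKM with the line as a random effect called 84. The same simulation of unchanged genotypes gave 3133 genes of 1 sign in both Tet2+/- lines, against 3631 here.

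Other lists were not called in Tet2+/- lines against the wild type. Members higher and lower in both lines were 3 and 7 of 23 DNA methylation machinery genes (camera adjusted p = 0.409), 6 and 11 of 45 imprinted genes (0.691; median -0.11, mean 0.18), 2 and 4 of 10 spongiotrophoblast and glycogen cell genes (0.673), 4 and 6 of 15 syncytiotrophoblast genes (0.650), 1 and 5 of 11 pluripotent stem cell markers (0.312) and 3 and 3 of 12 endoderm markers (0.582; median 0.2, mean -0.07). They were 0 and 2 of 7 fibroblast markers (0.827; median 0.08, mean -0.33), 3 and 5 of 29 epithelial genes (0.946), 5 and 6 of 32 cell cycle genes (0.946; median -0.03, test up), 3 and 4 of 26 p53 target genes (0.827), 3 and 1 of 24 interferon response genes (0.997; median -0.16, mean -0.23, test up), 4 and 9 of 27 hypoxia and glycolysis genes (0.827), 0 and 2 of 6 X inactivation and Y-linked genes (0.582) and 1 and 2 of 8 RNA quality genes (0.654). Adjusted over the list alone, 1 higher and 2 lower members of the spongiotrophoblast list, 1 higher imprinted gene and 1 lower RNA quality gene were called, and 0 members of the others. The linker histone gene Hist1h1c, an RNA quality gene whose message has a short poly(A) tail or none, was at 7.97 and 11.8 FPKM in Tet2+/- lines 1 and 2, at 17.9 and 23.1 in Tet2-/- lines 1 and 2 and at 36.6 in the wild type line.

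Both mutant genotypes were compared with the same 2 wild type libraries, which couples the results. Their log2 fold changes correlated across genes at 0.769 (genes are not independent replicates), where unchanged genotypes simulated with 1 shared wild type line gave 0.660. All lines were drawn anew there, and the wild type line was given the spread of the mutant lines. The covariance was 0.170 against 0.132, a difference of 0.0385. In all 4 mutant lines 981 genes were higher and 1231 lower than in the wild type, against 767 and 754 in the simulation and 265 and 440 for independent lists. The simulation holds the sharing of controls but assumes their spread, which 1 wild type line cannot check. The wild type libraries are too few to be split, so part or all of the excess may come from the shared wild type line. Counted in the same way against each of the other 4 lines, Tet2+/- line 2 reached 3340 genes and the wild type line 2212.

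The root mean square log2 difference was 0.598 between the Tet2+/- lines and 0.388 between the Tet2-/- lines, against 0.383 to 0.682 between lines of different genotypes. Between Tet2+/- lines 1 and 2, 3612 genes were higher and 3621 lower in line 1 (limma on libraries; 4193 and 3080 with upper quartiles). The interferon-induced membrane genes Ifitm3 and Ifitm2 were at 97.3 ± 9.6 and 146 ± 3.2 FPKM in line 1 and at 0.425 ± 0.13 and 3.5 ± 0.9 in line 2. Meg3 and Rian were at 78.1 and 40 against 0.205 and 0.138, and the NADPH oxidase subunit gene Cyba at 92.8 against 2.6. Hn1, the retinoic acid hydroxylase gene Cyp26a1, Pecam1, the steroidogenic Cyp11a1 and Ly6a were higher in line 2: Hn1 was at 34.2 against 0.302, Cyp26a1 at 102 against 6.4, Pecam1 at 41.7 against 3.04, Cyp11a1 at 76.6 against 6.54 and Ly6a at 65.8 against 5.52. Interferon response genes (19 higher and 3 lower in line 1 of 24; camera adjusted p = 1.60e-05) and p53 target genes (23 and 1 of 26; 7.96e-06) were higher in line 1, as were epithelial genes (20 and 4 of 29; 2.87e-04), fibroblast markers (7 and 0 of 7; 7.85e-04) and imprinted genes (27 and 10 of 45; 2.56e-03). Trophoblast stem cell factors (5 and 19 of 27; 1.60e-03), trophoblast giant cell genes (3 and 11 of 14; 3.87e-03) and FGF-ERK response genes (6 and 14 of 21; 0.0198) were lower in line 1. The giant cell call rested on the 5 members that met the filter on FPKM only through line 2: with the other 9 it was lost (3 and 6; adjusted p = 0.226). With an estimated correlation the p53 list kept a call (adjusted p = 0.0475), and the adjusted p of the others were 0.157, 0.389, 0.270, 0.270, 0.270, 0.283 and 0.357 in that order. Cdx2, a trophoblast stem cell factor, was at 27.9 FPKM in line 1 and 71.3 in line 2, and the giant cell hormone gene Prl2a1 at 0.591 and 13.8.

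Between Tet2-/- lines 1 and 2, 3630 genes were higher and 2260 lower in line 1, a split that scaling changed: it was 2950 and 2854 with medians of ratios and 2762 and 3006 with upper quartiles. Igfbp6, Timp1, Wdfy1, Crip1 and Cyba were higher in line 1, with Igfbp6 at 27.5 ± 1.5 against 5.3 ± 0.44 FPKM and Timp1 at 36.4 against 7.85. The imprinted growth inhibitor gene Grb10 (chromosome 11, 11830502 to 11937423) was at 14.7 ± 0.5 in line 1 and 142 ± 2.2 in line 2. The neurofilament gene Nefl was at 0.547 against 15.7, the matrix gene Thbs1 at 0.261 against 9.09, and Il5ra was lower in line 1 by a log2 fold change of -2.70 (SE 0.091). Atp6v0c-ps2, a pseudogene that can share reads with its parent gene, met the naming rule but had an SD of 4.7 around 8.21 FPKM in line 2. Epithelial genes were lower in line 1 (5 higher and 20 lower of 29; camera adjusted p = 5.29e-07), with the cadherin gene Cdh1 lower by a log2 fold change of -1.17. Trophoblast stem cell factors were lower (4 and 15 of 27; 1.67e-03), and so were FGF-ERK response (3 and 11 of 21; 0.0260), giant cell (3 and 7 of 14; 0.0270), spongiotrophoblast (2 and 5 of 10; 0.0437) and p53 target genes (7 and 14 of 26; 0.0208). Cholesterol synthesis genes (15 and 0 of 23; 6.07e-04) and hypoxia and glycolysis genes (16 and 4 of 27; 0.0340) were higher in line 1. None kept a call with an estimated correlation (adjusted p of 0.137 to 0.348). With the filter on FPKM met whichever line was left out, the giant cell, spongiotrophoblast and hypoxia calls were lost (adjusted p = 0.0875, 0.0514 and 0.0586).

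Imprinted genes differed by whole lines. Meg3, Rian and Mirg, non-coding RNAs of the cluster on chromosome 12, were at 76.8, 47.5 and 19.5 FPKM in Tet2-/- line 1, at 28, 21.8 and 9.03 in Tet2-/- line 2 and at 78.1, 40 and 21.7 in Tet2+/- line 1. They were at 0.205, 0.138 and 0.0174 in Tet2+/- line 2 and at 0.435, 0.259 and 0.102 in the wild type line. Ndn on chromosome 7 had the same low lines, at 0.0402 and 0.0669 FPKM against 5.01 to 9.61. Blcap was at 1.77 FPKM in the wild type line and 4.94 to 20.4 elsewhere, and Ascl2, a factor of the trophoblast lineage, at 0.48 in Tet2+/- line 2 against 3.02 to 6.07. Mcts2 was at 11.5 in Tet2-/- line 2 against 1.03 to 2.03.

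**Figure D4:**
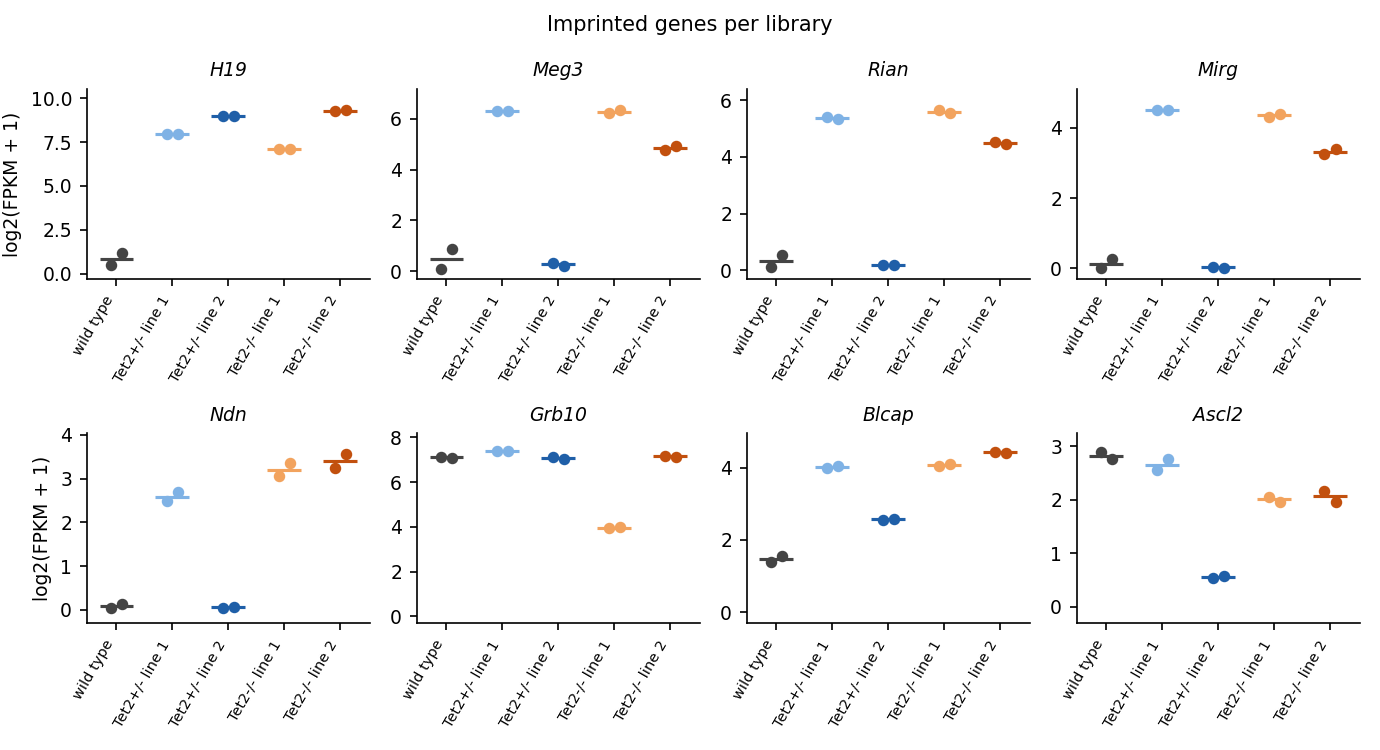
log2(FPKM + 1) of 8 imprinted genes per library (points), with horizontal lines at the line means. H19 is near 0 in the wild type line alone; Meg3, Rian, Mirg and Ndn are near 0 in the wild type line and Tet2+/- line 2; Grb10 is low in Tet2-/- line 1 and Ascl2 in Tet2+/- line 2.

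Expression of whole chromosomes also differed by line. In Tet2-/- line 1 the 929 tested genes of chromosome 11 had a median log2 shift of 0.248 against the mean of the other 4 lines. In Tet2+/- line 2 the genes of chromosomes 7, 9 and 15 had median shifts of -0.222, -0.211 and -0.207. All 4 lay outside the range of 10000 random gene sets of equal size. Lying outside was common: it held for 18 chromosomes in Tet2+/- line 2 and 10 in Tet2+/- line 1. It held for 10 and 8 in Tet2-/- lines 1 and 2, and for 7 in the wild type line.

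**Figure D5:**
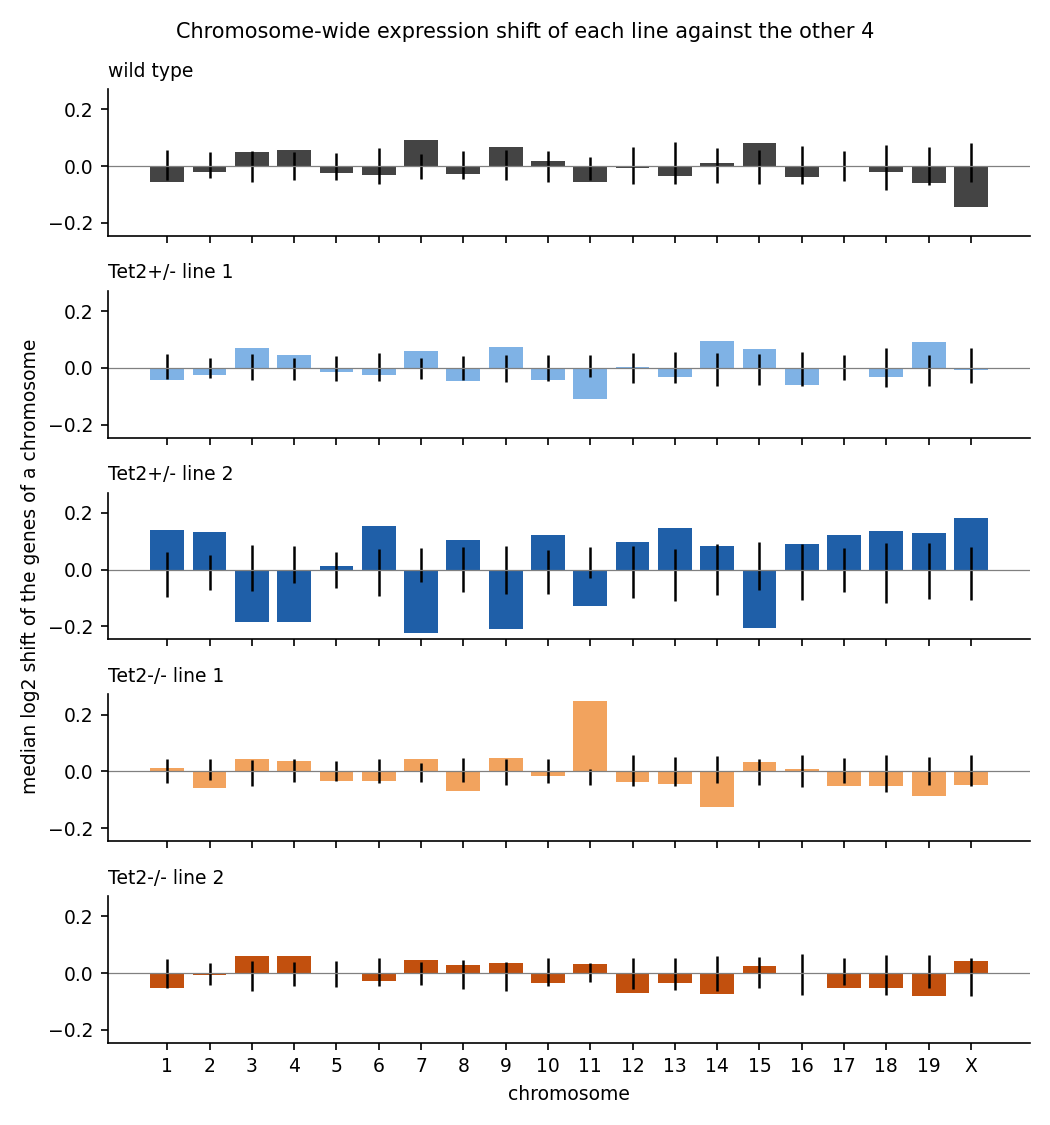
Median log2 shift of the tested genes of each chromosome in each line against the mean of the other 4 lines (bars), with the range of 10000 random sets of as many genes (vertical lines). Chromosome 11 stands at 0.248 in Tet2-/- line 1, and chromosomes 7, 9 and 15 stand at -0.222, -0.211 and -0.207 in Tet2+/- line 2.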

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

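The tests of the imprinted genes were chosen after their values were seen.

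Lines of 1 genotype departed from the wild type line in opposite directions at many genes. By limma on libraries, 488 genes were higher than in the wild type in 1 Tet2-/- line and lower in the other (265 higher in line 1, 223 higher in line 2), and 995 genes did so in the Tet2+/- lines (495 and 500). Such genes stand out because each line was called against the wild type with a different sign. Groups of 2 libraries are too small for a search for single deviating samples.

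Gene list members that differed from the wild type by at least 1.5-fold each way were all higher in line 1 than in line 2 for the Tet2+/- lines. This depends on the cut-off. Just below it Cdh2 was lower in line 1 (line 1 over line 2 log2 fold change -1.16), with members of both directions further down. The tight junction gene Cldn7 had a line 1 over line 2 log2 fold change of 3.17, the transcriptional coactivator gene Cited1 of 3.12 and the gap junction gene Gjb2 of 2.36. Cyr61 and Ctgf, secreted proteins of the matrix, had 2.44 and 2.06 (Ctgf at 10.6 and 1.8 FPKM). The interferon-induced Isg15 had 2.08, the receptor gene Pdgfrb 1.65 and the stress gene Gadd45b 1.55. The imprinted Plagl1, Cdkn1c and Igf2 had 1.95, 1.81 and 1.65; Igf2 was at 1517 FPKM in line 1, 483 in line 2 and 926 in the wild type line. Between Tet2-/- lines 1 and 2, Gjb2 had a log2 fold change of 1.49 and the imprinted Gatm of -1.47.

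The imprinted genes that were low in whole lines, at under 0.1 of a highest line of at least 5 FPKM, numbered 9; Plagl1, whose highest line was at 3.75 FPKM, also fell under 0.1 but not within that floor. Genotype is argued against for 7 of the 9 genes, whose low lines were not all the lines of a genotype. Examples are Grb10 in Tet2-/- line 1 alone and Meg3 in Tet2+/- line 2 and the wild type line. These 7 are not separate cases, since Meg3, Rian and Mirg belong to 1 cluster and share their low lines. Mcts2 was high in Tet2-/- line 2 (11.5 FPKM) and at 1.03 to 2.03 elsewhere, so its low lines depend on the cut-off. For H19 and Blcap, low in the wild type line only, genotype and line cannot be told apart with 1 wild type line. The imprinted list's median SD between lines (0.463) lay at percentile 100 of random lists of equal expression, but 15 of the 20 lists lay above the 99th, so variability is not particular to imprinted genes. A change of imprint in single lines may underlie the pattern and stays untested, since neither DNA methylation nor alleles were measured, and reads of the Mcts2 retrogene may be shared with its parent gene.

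The deposited counts of Tsix, from 834 to 3389 per library, stand out in values that limma on FPKM does not use; they lie opposite the abundant Xist transcript, and Tsix itself was listed at 0.017 to 0.148 FPKM.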

How the results depend on the processing

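Limma on FPKM with the line as a random effect, scaled FPKM, estimated fragments, centred chromosomes, a filter on FPKM met whichever line was left out and the omission of Tet2+/- line 2 from counts of shared genes were chosen after the results were seen.

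Between genotypes, limma between lines called 1 gene for Tet2-/- against Tet2+/-, 0 for Tet2-/- against wild type and 0 for Tet2+/- against wild type. At an unadjusted p under 0.05 there were 305, 652 and 655, where chance alone would give a share of 0.05 of the 10904 tested genes. With libraries as replicates the counts of called genes were 861, 1678 and 1596, and 560, 1245 and 1125 with the replicate number as a block. These treat libraries of 1 line as independent. EdgeR on the deposited counts called 0, 0 and 0 (also with DESeq2 size factors and upper quartiles), 2, 7 and 9 with no filter, 0, 47 and 27 with only the genotypes compared, 47, 200 and 247 with libraries as replicates, and 31, 152 and 172 with the block added. DESeq2 called 4, 14 and 18, limma-voom with the line as a random effect 18, 52 and 99, and limma on FPKM with the line as a random effect 6, 72 and 84. Without a filter on FPKM, and on estimated fragments, the first comparison had 0 calls, and 2 with the filter met whichever line was left out. Leaving out a line or library gave 0 to 18 calls in the first comparison (18 without Tet2+/- line 1; 0 without either Tet2-/- line, Tet2+/- line 2, the first library of Tet2-/- line 2 or the second of Tet2+/- line 2), 0 to 0 in the second and 0 to 55 in the third (55 without Tet2+/- line 1). The deposited counts cannot be taken as the same expression read at lower depth, so their numbers do not check those on FPKM. The causes of these differences were not tested.

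Between lines, edgeR and DESeq2 on the deposited counts called fewer genes than limma on FPKM. These counts hold few of the reads, at a median of 2.53% of the estimated fragments, and are 0 at Eomes. Their numbers are therefore no check of the FPKM results. The counts that follow are, in order, edgeR with TMM, DESeq2 size factors, upper quartiles, no filter, a replicate block and only the lines compared, then DESeq2. Tet2-/- line 1 against wild type had 1042, 1050, 1028, 950, 1160, 1047 and 290 (6135 on FPKM; 5048 to 5291 leaving out a library of the lines compared, as in the ranges below). Tet2-/- line 2 against wild type had 1359, 1356, 1346, 1242, 1483, 1365 and 409 (7112; 6226 to 6386). Tet2+/- line 1 against wild type had 880, 877, 877, 789, 1008, 892 and 196 (5937; 4768 to 5020). Tet2+/- line 2 against wild type had 2123, 2120, 2106, 2055, 2238, 1973 and 745 (7741; 6936 to 7075). The Tet2-/- lines against each other had 697, 706, 697, 603, 819, 772 and 142 (5890; 4813 to 4976), and the Tet2+/- lines 1734, 1730, 1719, 1676, 1836, 1600 and 547 (7233; 6408 to 6453).

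Genes called in every pair of a Tet2-/- with a Tet2+/- line numbered 61, 61, 59, 48, 83, 43 and 16 in the same order (1001; 761 to 868 leaving out a library of those lines, 1007 and 1008 without a wild type library, 1183 with the replicate block on FPKM; 2988 without Tet2+/- line 2, where fewer comparisons must be passed). With chromosomes centred there were 804, of which 575 were shared. Both Tet2-/- lines against wild type had 549, 556, 545, 485, 627, 550 and 177 (4175; 3365 to 3906, and 4111 to 4127 without a Tet2+/- library), and both Tet2+/- lines 516, 515, 513, 451, 587, 502 and 119 (3631; 2874 to 3361, and 3582 to 3607 without a Tet2-/- library; 5937 without line 2).

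The Tet2 log2 fold change, -0.13 for Tet2-/- over Tet2+/-, ranged from -0.29 to 0.035 over omissions and was 0.035 without Tet2-/- line 2. Camera called 4, 4 and 6 lists in the genotype comparisons in order, and 0, 0 and 0 with an estimated correlation. With libraries as replicates it called 1 in the first, with the block 1 in the first and 3 in the third. Omissions gave 3 to 8 (8 without Tet2-/- line 1 or Tet2+/- line 1), 2 to 7 (7 without Tet2-/- line 1, 2 without line 2) and 6 to 9. Of 14 called list results, 261 values kept direction and call, 35 lost the call and 2 changed direction, without Tet2+/- line 2: fibroblast markers (adjusted p = 0.997; 1.24e-05 to 0.997 over omissions) and interferon response genes (0.602; 3.48e-07 to 0.602) for Tet2-/- over Tet2+/-.

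The 103 named gene results leave out Tet2 for Tet2-/- over Tet2+/-, which is given above. Recomputed on FPKM and estimated fragments only, 2460 of their values kept direction and call. Of the others, 156 gained a call, 11 lost it and 9 changed sign, all of uncalled genes. For Tet2-/- over Tet2+/-, Tet1 became 0.089 without Tet2-/- line 2 and 0.020 without Tet2+/- line 1 (-0.34 to 0.089 over omissions). Tet3 became 0.16 and 0.038 there (-0.27 to 0.16) and 0.017 with chromosomes centred, and Dnmt3l became -0.24 without Tet2+/- line 2 (-0.24 to 0.54). For Tet2+/- over wild type, Dnmt1 became 0.020 with medians of ratios, 0.035 on estimated fragments and 0.12 with chromosomes centred.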

Other observations

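The tests of the Tet2 transcript, of depth as the source of the chromosome shifts and of the other pairings for called genes were chosen after those results were seen; the tests of gain or loss, of GC content and length, of the segment around Tet2 and of the pairings for genes in every line pair were set beforehand.

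Tet2+/- line 2 stood furthest apart. Against each of the other 4 lines 3340 genes were called with 1 sign in it (1633 higher, 1707 lower; limma on libraries), against 2212 in the wild type line, 1431 in Tet2-/- line 2, 1008 in Tet2-/- line 1 and 961 in Tet2+/- line 1. The glucose transporter gene Slc2a3 was at 5.03 FPKM in Tet2+/- line 2, 11.6 and 33.2 in Tet2-/- lines 1 and 2, 113 in Tet2+/- line 1 and 102 in the wild type line; it was chosen after its values were seen. Tagln, a smooth muscle and fibroblast marker, was at 0.487 FPKM in Tet2+/- line 2 and 5.89 to 13.9 elsewhere.

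The Tet2 transcript was present in the lines labelled Tet2-/-. Too few reads are argued against, since the lowest of the deposited lower 95% bounds in their 4 libraries was 0.914 FPKM. A transcript still made from the changed allele may account for it, as the mean of these lines was 0.758 of the wild type level, but the labels name no allele and reads per exon were not analysed here. Mislabelled lines are not excluded either: the lowest line had 0.611 of the highest, so no line stood out as lacking Tet2. These explanations cannot be told apart here.

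Shifts of whole chromosomes may reflect a gain or loss in all or part of the cells. There were 4 shifts over 0.2 on the log2 scale beyond all random sets, as gain or loss predicts: chromosome 11 in Tet2-/- line 1 and chromosomes 7, 9 and 15 in Tet2+/- line 2. The shifts ran along the length of each: from the first to the last part they were 0.315, 0.265 and 0.176 on chromosome 11 (80.3 to 91.9% of genes of 1 sign), -0.222, -0.230 and -0.218 on 7, -0.195, -0.213 and -0.234 on 9, and -0.208, -0.227 and -0.177 on 15 (75.6 to 81.5% of 1 sign). GC content and transcript length are argued against as the whole cause. After their trend was removed, 3 of the 4 stayed over 0.2 (chromosome 15 moved from -0.207 to -0.186). For a factor of depth or scaling per library, 4 of the 4 lay outside sets from other chromosomes. This repeats the count given for gain or loss, and each line's median had been subtracted beforehand. It therefore decides nothing about such a factor. Tet2+/- line 2 had 18 of 20 chromosomes beyond the random sets (12 higher, 6 lower), and the other lines had 7 to 10. DNA was not measured, and the shifts are smaller than a whole gain or loss in all cells would give. Regulation over broad regions therefore stays open.

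Other pairings of the 4 mutant lines are too few, at 3 with the real one, for a share under 0.05. Limma between lines called 1 gene for the real grouping and at most 0 for the others, so 1 of the 3 gave as many. Genes called in every line pair numbered 1001 for the real grouping and at most 1497 for the others, and all 3 gave as many; the highest paired line 1 of each genotype against line 2 of each.

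Genes near Tet2 could differ because a segment of the targeted chromosome was carried along. Within 10 Mb of Tet2 3 of 49 tested genes (6.12%) differed in every line pair, against 958 of 10404 on other chromosomes (9.21%; two-sided Fisher's exact test, p = 0.622). The shares lie within counting error of each other, so the numbers near Tet2 are too small to decide.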
